A study of Mus musculus with 4 samples.

How the data were processed

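Enhanced crosslinking and immunoprecipitation (eCLIP) was used to find RNAs bound by DDX5, a DEAD-box RNA helicase, in mouse Th17 cells. Naive CD4 T cells from female C57BL/6 mice had been cultured for 72 h with antibodies to CD3 and CD28 and with IL-6 and TGF-β, per the labels' protocols. The mice were 8 weeks old, and the titles call all samples WT (wild type). Cells were crosslinked with ultraviolet light, RNA was trimmed with limited RNase, and DDX5 complexes were pulled down before library construction. The series holds 4 libraries, namely 2 DDX5 immunoprecipitates (IP) and 2 inputs, with the replicate numbers 1 and 2 in both groups. The samples were grouped by their titles. The labels do not say whether the replicates are separate mice or 1 pool of cells that was split. No read counts or library totals were in the files used here, so the depth per library is unknown and no interval that needs it is given.

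The submitters' processing notes name cutadapt 1.9.1, STAR 2.4.0i, SAMtools 1.4.1 and the mouse genome build mm10. Per the deposited settings, each IP library was normalised to its own input, both replicates were then joined by the irreproducible discovery rate method, and peaks needed a log2 fold of at least 3 and a −log10 p of at least 3. The settings also give a random barcode of 10 nt on each read and switch off a separate mapping to repeat elements. The peak caller, the reproducibility threshold, the annotation release and the rule that combined the replicates into 1 value are not given in the sources used here. The deposited peak list gives 1 log2 fold enrichment of IP over input and 1 −log10 p per peak, per the file headers, and no value for a single replicate. Both are the authors' own peak values and are used only to describe, rank, filter and compare peaks within this list. A −log10 p of 400 is the highest in the list and acts as a ceiling, reached by 72 peaks. A further deposited file held only the settings of the processing run and no measured values. A planned comparison of IP with input per RNA family, a comparison of replicate 1 with replicate 2, and every alternative without 1 replicate could therefore not be run.

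Peak starts were read as counted from 0 and are printed counted from 1 on mm10. Region classes are the authors' own annotation, in which an intronic peak is near a splice site or deep. By the intron coordinates in the same file, peaks called near lay up to 498 nt from the closest splice site. Peaks called deep lay as little as 403 nt from one, so the classes overlap in distance. Where the annotation named several genes for 1 peak, the peak counted for each of them. Of 461 gene identifiers, 460 were found in a table of Ensembl names when version numbers were ignored. Of 459 gene symbols, 423 matched the RefSeq gene table of GRCm38.p6, directly or through a unique synonym. The background for gene lists was the 21900 protein-coding genes of that table, of which 396 carried a peak. A peak was counted as lying in a small RNA gene when it overlapped, on the same strand, a feature annotated as snoRNA, scaRNA, snRNA or rRNA by at least 1 nt. No genome sequence was used, so GC content, G-runs, short sequence words and the placement of peaks against exon and intron lengths were not analysed here.

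Shares of peaks are given with exact Clopper-Pearson 95% intervals, which cover counting error only. Peaks from 1 gene are not independent, and neighbouring peaks can be pieces of 1 binding site. Enrichment was compared between region classes by a two-sided permutation test with 100000 resamples on the difference of medians, after averaging peaks of a gene within a class. Gene lists were tested for the share of members with a peak by two-sided Fisher's exact tests, and for peak height by a two-sided permutation test on the mean over genes of the highest peak. The height test was run for lists with at least 5 members with a peak. P values were adjusted by the Benjamini-Hochberg method within each family of tests, with a threshold of 0.05. The lists, the region classes, the tests and the rule for named genes were fixed before the data were examined. The rule names the 12 genes with the most peaks, the 12 with the highest peak enrichment, up to 4 members of each list by enrichment, all members of the Th17 list with a peak, and Ddx5, Ddx17, Rmrp, Il17a, Il17f, Hif1a, Il10, Foxp3, Stat3, Malat1 and Neat1 in any case. A further item of this rule is not reported here. Lists of ribosomal protein, histone, small nucleolar RNA and microRNA genes were made by symbol pattern, and the histone pattern also takes in variant histones such as H2afz.

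The position of peaks along genes was added after the data were examined. For peaks outside small RNA genes, the distance of the midpoint from the 5′ end of the longest overlapping protein-coding transcript was set against uniform placement along the same transcript, drawn 1000 times. Gene means of the relative position were compared with the middle of the transcript by a two-sided sign-flip test with 100000 resamples. Settings varied by prior choice were a stricter log2 fold (4.0), a stricter −log10 p (5.20), other overlap rules, every peak counted once, a background matched on gene length in 10 bins with an exact stratified test, and the mean of a gene's peaks in place of the highest. Settings added later were peaks up to 10 nt apart joined into 1 site, removal of peaks under 30 nt, removal of peaks in small RNA genes, and RefSeq small RNA coordinates.

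The tests were tried on simulated data. For random lists of 30 among 21900 genes, Fisher's test called 2.5% of 200 lists with no effect, 52% at 5 times the odds and 92% at 10 times the odds, so lists of this size with smaller effects can be missed. For 15 of 459 genes with a peak, the permutation test of the mean called 7% of 200 simulations with no shift and 99% with a log2 shift of 1. Both trials counted unadjusted p values under 0.05, so fewer real effects would be called after the adjustment used in the results. Computation used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.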

Results

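The RNAs bound by DDX5 in cultured Th17 cells, the interleukin-17-producing class of helper T cells, were mapped by eCLIP. The data comprised 2 DDX5 IP libraries and 2 input libraries, and the list used here holds the 900 peaks that the authors found reproducible between replicates. Each peak has 1 enrichment value for both replicates, so no spread between replicates can be given, and the SD values below are over peaks or genes. The peaks named 459 genes and formed 741 sites when neighbours were joined. Median enrichment over input was 5.31 on the log2 scale (39.7-fold), with quartiles of 4.64 and 5.84. Peaks were 2 to 243 nt wide, with a median of 65 nt.

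The first question was where in RNAs DDX5 peaks lie. Introns held most of them, with 532 of 900 peaks (59.1%, 95% interval 55.8 to 62.3). Of these, 271 peaks lay deep in introns of protein-coding genes (30.1%, 27.1 to 33.2) and 242 near a splice site (26.9%, 24.0 to 29.9). The 5′ UTRs held 149 peaks (16.6%, 14.2 to 19.1) in 103 genes, whereas 3′ UTRs held only 11 peaks (1.22%, 0.612 to 2.18) in 9 genes. Coding exons held 93 peaks (10.3%, 8.42 to 12.5) and exons of noncoding RNAs 111 (12.3%, 10.3 to 14.7). Introns of noncoding genes held 19 peaks, and 4 peaks at 1 site on chromosome 7 (130834455 to 130834494) lay outside genes. The 5′ UTR class is not purely exonic, since 88 of the 149 peaks also lay inside an intron of another transcript (59.1%). The share of exons of noncoding RNAs fell to 7.90% among peaks with a log2 enrichment of at least 4.0.

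**Figure D1:**
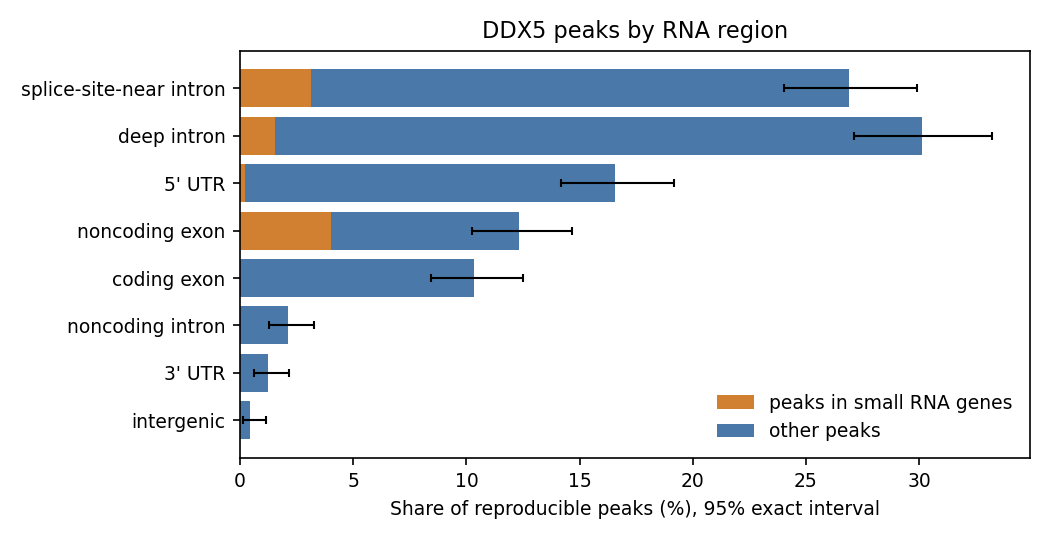
Share of the 900 reproducible DDX5 peaks (%, horizontal axis) in each RNA region, with exact 95% intervals as bars and the part in small RNA genes in orange. Deep introns (30.1%) and introns near splice sites (26.9%) hold the most peaks, and 3′ UTRs 1.22%.

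The height of peaks differed between regions, but as a fold over input it can depend on input coverage, which was not available. Deep intron peaks were higher, with a median of gene means of 5.49 on the log2 scale against 5.14 for other peaks (133 and 402 gene and class means, difference 0.35, permutation adjusted p = 0.00098). A gene with peaks in several classes gave a mean to each. The test treated these means as independent, so the p values of this comparison are approximate. Peaks in noncoding exons were lower, at 4.80 against 5.27 (43 and 492 means, difference −0.47, permutation adjusted p = 0.00388), and the difference was −1.23 with every peak counted once. Coding exon peaks had a median of 5.0 against 5.27 and missed the threshold (permutation adjusted p = 0.0977). The 5′ UTR (5.18 against 5.27), 3′ UTR, noncoding intron and splice-site-near classes did not pass the test either, with permutation adjusted p values of 0.502, 0.462, 0.462 and 0.775. Without peaks in small RNA genes, the noncoding exon call was lost (difference −0.26, permutation adjusted p = 0.337) and the coding exon class became lower than the rest (difference −0.36, permutation adjusted p = 0.00896).

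A small set of genes held many peaks, and the 12 with the most took 18.6% of the list, while 283 of the 459 genes had 1 peak. Among protein-coding genes, Ski had the most, with 25 peaks on the minus strand of chromosome 4 between 155169832 and 155222584. Ski encodes a repressor of TGF-β signalling. Its mean log2 enrichment was 5.84 ± 0.56 (SD over 25 peaks) and its highest peak reached 7.24 (151-fold), and 21 of its peaks were deep intronic. Satb1, a chromatin organiser of T cells, had 20 peaks (mean 5.68 ± 0.71, SD), of which 14 were in 5′ UTRs. Pmepa1, a TGF-β-induced membrane protein, had 12 (5.85 ± 0.73), Furin, a proprotein convertase, had 10 (5.98 ± 0.73), and Hdac7, a class IIa histone deacetylase, had 10 (5.52 ± 0.84). Bcl11b, a transcription factor of T cell identity, had 9 peaks (5.67 ± 0.28). Chd7, Map3k1 and Zeb1 had 8 each, with means of 5.87 ± 0.48, 5.72 ± 0.61 and 6.29 ± 0.37.

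**Figure D2:**
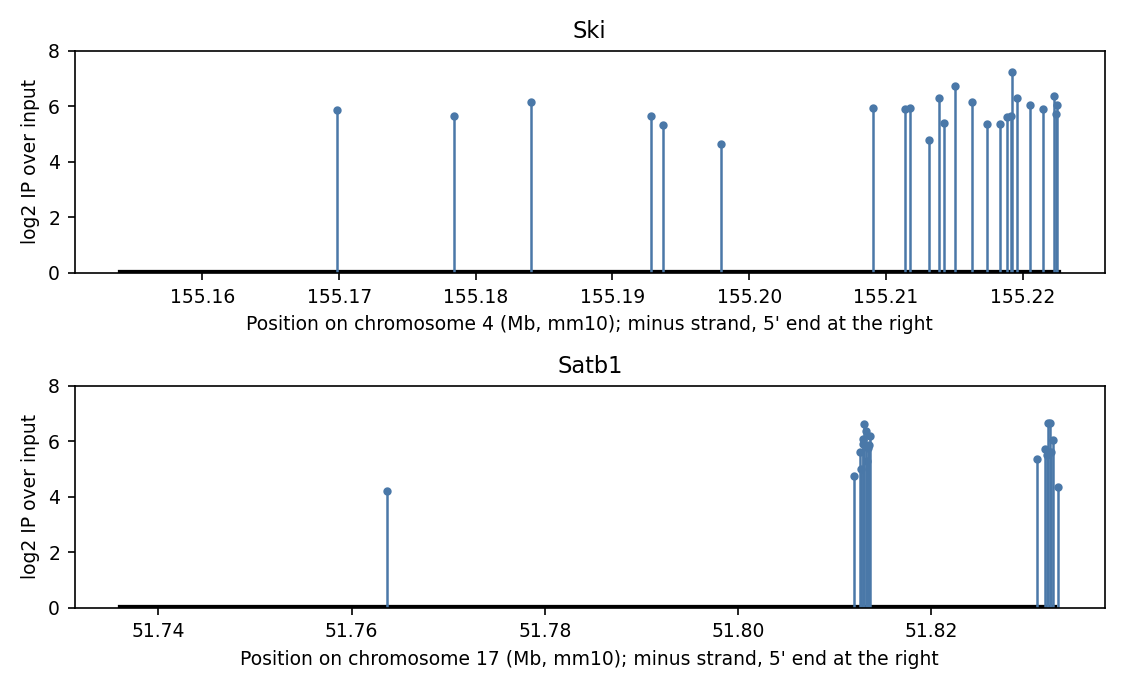
Peaks of Ski (25) and Satb1 (20), with the longest overlapping transcript as a black line. The Satb1 peak that ends at 51833129 lies beyond the 5′ end of its line, at 51832672. The horizontal axis is the mm10 position in Mb and the vertical axis the log2 enrichment of each peak over input. Both genes lie on the minus strand, and 48% of Ski peaks and 40% of Satb1 peaks fall in the first of 10 equal parts of the transcript, at the right.

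Nuclear long noncoding RNAs carried peaks in 5 of the 19 listed. Neat1, the scaffold RNA of paraspeckles, had 13 peaks on chromosome 19 between 5824750 and 5845463, with a mean log2 enrichment of 6.11 ± 0.86 (SD) and a highest value of 7.19 (146-fold). Malat1, an abundant RNA of nuclear speckles, had 12 peaks in 6 sites (5.04 ± 0.78), of which 3 stood at the −log10 p ceiling. Xist, the RNA of the inactive X chromosome, had 4 peaks and a highest value of 5.97, and Dleu2 had 1 peak at 5.71. Gm26917 had the most peaks of any gene, 32 in 10 sites on chromosome 17 between 39843220 and 39845826, all at the ceiling and with a low mean log2 enrichment of 3.54 ± 0.39. These peaks, with 5 of Gm42418, flank the RefSeq locus Rn18s-rs5, an 18S ribosomal RNA-related sequence.

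The most enriched genes had mostly short, intronic peaks. Gm26636, a noncoding gene on chromosome 6, had the highest value, 9.45 on the log2 scale (700-fold), in a 39-nt peak at 87913901 to 87913939. The site outside genes on chromosome 7 reached 8.52 (368-fold). Among genes, the deep intron peak of Tex14 came after Gm26636 at 8.37, and it overlapped Rnu3b4, an annotated copy of U3 snoRNA. Slc22a22 (8.36), Plcb4 (8.29), Pdgfra (8.11), Arid4a (8.04), Cfap97 (7.75), Auts2 (7.71) and Peak1 (7.66) came next, each with 1 site of 25 to 52 nt that the list split into 2 or 3 peaks. The Peak1 site overlapped Gm24270, annotated as a microRNA or other small RNA. The last of the 12 were 9330185C12Rik (7.66), Pmepa1 (7.55) and Gm17018 (7.30). Of this group, only Pmepa1 was also among the genes with the most peaks.

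Peaks in protein-coding genes crowded at the 5′ end, a measure added after the data were examined. Of 722 peaks outside small RNA genes, 385 lay within 1 kb of the start of the longest transcript (53.3%, 49.6 to 57), against 4.24% for uniform placement and at most 7.06% in 1000 draws. Uniform placement ran over exons and introns alike and ignored how abundant each part of the RNA is. It is therefore a reference by length, not the level that chance would give in spliced RNA. Of 10 equal parts of the transcript, the first held 427 peaks (59.1%) and the last 23. Averaged by gene, the mean relative position was 0.172 ± 0.264 (SD over 369 genes), and 316 genes had a mean in the 5′ part (permutation p = 1e-05, the smallest that 100000 sign flips can give). At least 1 peak within 1 kb of the start was found in 243 of the 369 genes (65.9%). Of 257 deep intron peaks, a class that by definition leaves out sequence next to the first exon, 44 lay within 1 kb (17.1%, against 2.43% for uniform placement).

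**Figure D3:**
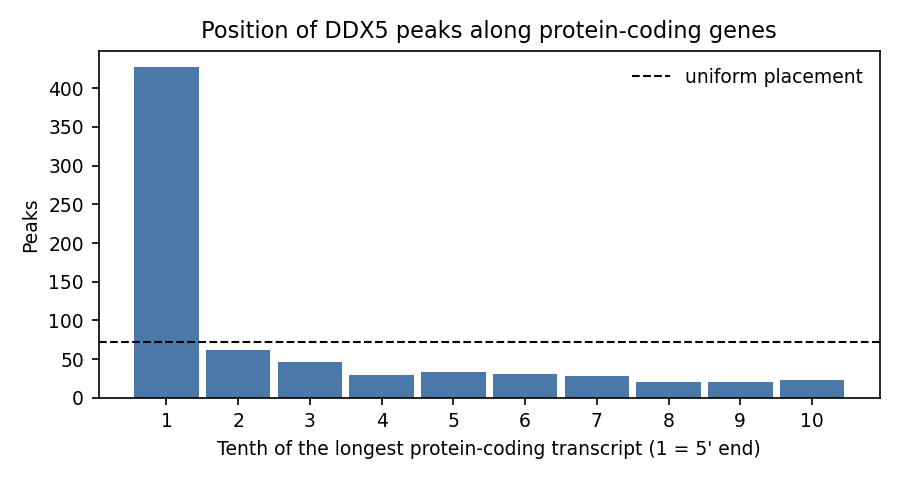
Number of peaks (vertical axis, 722 peaks outside small RNA genes) in 10 equal parts of the longest protein-coding transcript, from the 5′ end at the left. The dashed line marks uniform placement, and the first part holds 427 peaks.

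Small RNA genes held 80 peaks in 62 genes (8.89% of peaks, 7.11 to 10.9), and 42 of these peaks had been classed as intronic because the small RNA sits in an intron of its host gene. snoRNAs and scaRNAs took 50 peaks in 39 genes, snRNAs 7 peaks in 6 genes, and rRNA gene copies, mostly of 5S rRNA, 23 peaks in 17 annotated copies. Counts of copies are by mapped position, and reads of repeated RNAs can be placed at the wrong copy. Rnu3a, a U3 snoRNA needed for ribosomal RNA processing, had 4 peaks at the ceiling with a highest log2 enrichment of 3.31. Snord118, the U8 snoRNA, had 4 peaks with a highest value of 3.64 and Scarna2 had 2 with 4.53. The U7 gene Rnu7, whose product processes histone transcripts, had 1 peak at 3.28. Peaks in small RNA genes were lower than others, as a fold over input that can depend on input coverage. The medians of gene means were 4.17 and 5.29 (60 and 395 means, difference −1.12, permutation p = 1e-05, the smallest that 100000 resamples can give). Medians were 3.76 for peaks in snoRNAs and scaRNAs, 4.29 in snRNAs and 5.13 in rRNA copies. Of peaks with a log2 enrichment of at least 4.0, 5.27% were in small RNA genes.

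Host genes of snoRNAs carried peaks mainly through the snoRNAs themselves. Among 20 protein-coding hosts on the list, 10 had a peak against 0.362 for the average gene (odds ratio 55.6, 95% interval 20.6 to 150, Fisher adjusted p = 1.31e-11). With noncoding hosts, 13 members had a peak, and 12 of them, including Gas5, Snhg1, Zfas1, Nop56, Rpl13a and Rack1, had one within the small RNA. Rpl13a had 3 peaks, in Snord32a (4.15), Snord33 (3.40) and Snord34 (3.77), all on chromosome 7. Cytoplasmic ribosomal protein genes showed the same form, with a peak in 11 of 84 (odds ratio 8.39, 3.98 to 16.1, Fisher adjusted p = 1.68e-06). The odds ratio was 28.4 against genes of like length and 3.72 at a log2 enrichment of at least 4.0. All 11 had a peak in a snoRNA, and 9 had no other peak. The highest peaks of the list were those of Rpl4 (4.82, in a coding exon), Rpl23a (4.56, in Snord42b) and Rps3 (4.48, in Snord15b). Without peaks in small RNA genes, 2 of the 84 were left (odds ratio 1.42, Fisher adjusted p = 0.91), while the hosts kept an excess with 5 members (odds ratio 19.6, Fisher adjusted p = 7.12e-05). In the list of small nucleolar and Cajal body RNA genes, 3 of 142 were named by the authors' annotation (Scarna2, Snord47 and Snord118), fewer than overlapped a peak, because the annotation mostly names the host.

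The gene lists asked which programmes of the T cell are represented among bound genes. RNA must be present to be bound, and no expression level was available, so an excess over all protein-coding genes cannot separate binding from expression. Housekeeping genes, included as a rough reference for expressed genes, had peaks in 4 of 20 (odds ratio 13.7, 3.32 to 42.7, Fisher adjusted p = 0.00113), namely Ywhaz, Eef1a1, Actb and Hsp90ab1. Whether their excess came from expression or from binding was not tested. Of 25 lists of protein-coding genes, 14 lay above background and 0 below.

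Genes of T cell identity and receptor signalling had peaks in 7 of 34 (odds ratio 14.3, 5.23 to 33.9, Fisher adjusted p = 8.82e-06). Beside Satb1 and Bcl11b these were Nfatc2 (highest log2 enrichment 6.15), Malt1 (6.02), Bach2, Tcf7 and Ets1. Against genes of like length the odds ratio of this list was 9.59 (exact stratified adjusted p = 0.000146), below the 19.9 of housekeeping genes, a difference that was not tested. Cytokine receptors and JAK-STAT genes had peaks in 8 of 26 (24.6, 9.19 to 59.9, Fisher adjusted p = 1.04e-07), led by Il21r (5.67), Il4ra (5.56), Socs1 (5.43) and Jak3 (5.36), and including Stat5b, Jak1, Ptpn2 and Il2rb. The Th17 programme had 3 of 32 (5.65, 1.10 to 18.4, Fisher adjusted p = 0.0353). Its members were Rora, a nuclear receptor, with 5 peaks and a highest value of 6.49 in a 5′ UTR, Ahr with 1 5′ UTR peak at 4.93, and Hif1a with 3 deep intron peaks up to 4.6. Against genes of like length the Th17 odds ratio was 4.85 and no longer passed the threshold (exact stratified adjusted p = 0.0547). Il17a, Il17f, Il10, Foxp3, Stat3, Rmrp, Ddx5 and Ddx17 had no peak in the list, which is no evidence that DDX5 did not bind them.

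Treg markers had peaks in 2 of 18 (odds ratio 6.82, 0.758 to 29.1, Fisher adjusted p = 0.0687), namely Il2ra with 7 deep intron peaks up to 5.52 and Ctla4 at 4.92. Th2 markers had 1 of 10, Il4ra (Fisher adjusted p = 0.245), and Th1 markers 0 of 12 (Fisher adjusted p = 1). Markers of B cells (0 of 11), myeloid cells (0 of 14), cytotoxic and NK cells (0 of 13) and erythroid cells (0 of 10) had none. Together these are 0 of 48 where 0.868 would come from the average gene, so their absence was within chance (Fisher p = 1).

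**Figure D4:**
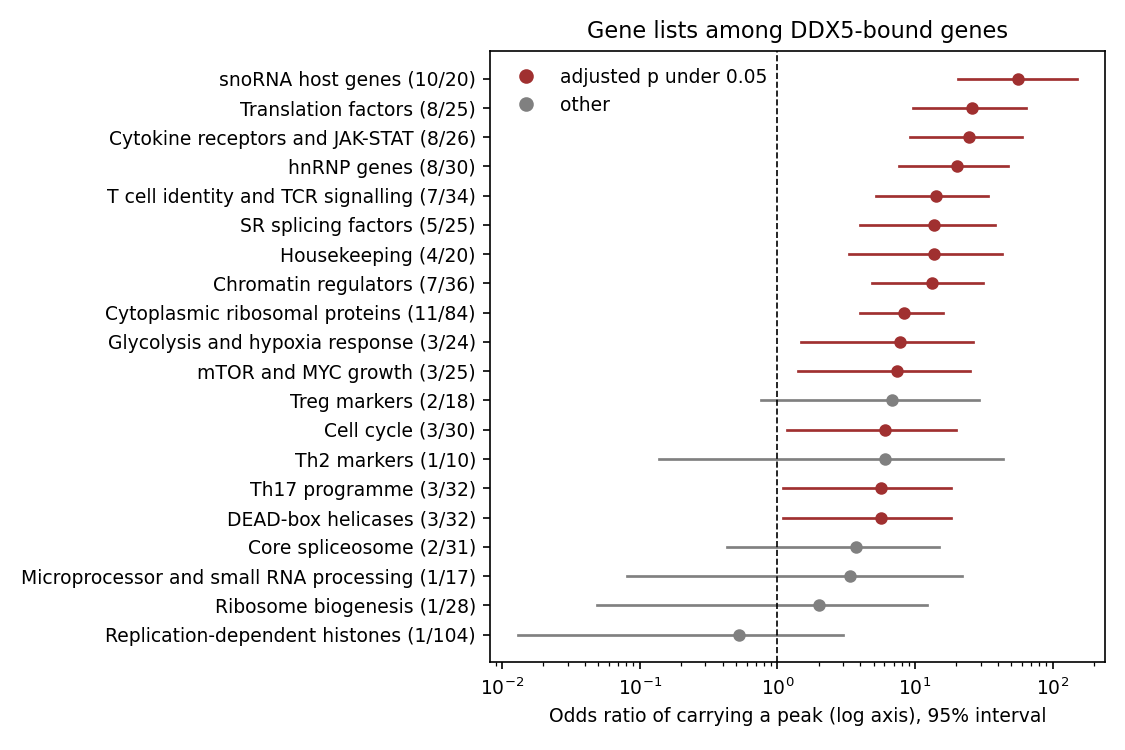
Odds ratio of carrying a DDX5 peak (log axis) for each list with at least 1 member bound, against other protein-coding genes, with 95% intervals as lines and members with a peak over all members in brackets. Red marks an adjusted p under 0.05, and housekeeping genes stand at 13.7, between the lists of SR splicing factors and chromatin regulators.

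RNA-processing genes were themselves among the bound RNAs. hnRNP genes had peaks in 8 of 30 (odds ratio 20.1, 7.70 to 47.3, Fisher adjusted p = 2.75e-07), with Hnrnpf highest (7.23, 5 peaks), then Matr3 (6.32), Hnrnpk (6.20) and Hnrnpa3 (5.85). SR splicing factors had 5 of 25 (13.7, 4.01 to 38.0, Fisher adjusted p = 0.000232), including Srsf4 (6.53), Srrm2 (5.95), Luc7l2 (5.25) and Tra2a (4.39). Core spliceosome genes did not pass the test, with 2 of 31 (Snrnp70 at 5.33 and Prpf38b at 4.11, Fisher adjusted p = 0.168). Other DEAD-box genes with a peak were Eif4a1 (6.00), Ddx39b (5.13) and Eif4a2 (4.56), 3 of 32 (5.65, 1.10 to 18.4, Fisher adjusted p = 0.0353). All 3 carried a snoRNA peak, and the DEAD-box excess no longer passed the threshold without small RNA peaks (odds ratio 3.88, Fisher adjusted p = 0.17). Of microprocessor and small RNA processing genes, 1 of 17 had peaks (Fisher adjusted p = 0.371), Ago2 with 5 and a highest value of 6.11.

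Among growth genes, translation factors had peaks in 8 of 25 (odds ratio 26.0, 9.67 to 64.1, Fisher adjusted p = 1.04e-07). Eif4e, the cap-binding factor, led with 6.76 near a splice site, followed by Eif5 (6.17), Eif5a (5.85) and Eif4g2 (5.70). Chromatin regulators had 7 of 36 (13.3, 4.89 to 31.3, Fisher adjusted p = 1.14e-05), with Arid1a (6.04, 7 peaks) and Ezh2 (5.50) after Chd7 and Hdac7. Against genes of like length, the odds ratio of chromatin regulators was 7.22 (exact stratified adjusted p = 0.000397) and that of housekeeping genes 19.9. Glycolysis and hypoxia genes had 3 of 24 (7.81, 1.49 to 26.3, Fisher adjusted p = 0.0224), namely Egln3 (6.18), Hif1a and Aldoa (3.82). The mTOR and MYC list had 3 of 25 (7.45, 1.42 to 25, Fisher adjusted p = 0.0228), Mxi1 (5.03), Foxo1 (4.80) and Myc (4.74). With length matching its odds ratio was 5.21 and no longer passed the threshold (exact stratified adjusted p = 0.051). The glycolysis and hypoxia excess no longer passed the threshold at a log2 enrichment of at least 4.0 (odds ratio 5.31, Fisher adjusted p = 0.103). Cell cycle genes had 3 of 30 (6.07, 1.17 to 19.9, Fisher adjusted p = 0.0346), Cdkn1a (5.43), E2f3 (5.38) and Mki67 (4.95). Ribosome biogenesis genes had 1 of 28 (Nop56, in its snoRNA, Fisher adjusted p = 0.527) and histone genes 1 of 104 (the variant histone gene H2afz at 5.08, Fisher adjusted p = 1). By the authors' gene names, no peak was assigned to any of the 13 Pol III and structured noncoding RNAs, the 15 mitochondrially encoded genes or the 1193 microRNA genes on the lists. Such names can miss a small RNA inside a host gene, and the 23 peaks in rRNA gene copies, mostly of 5S rRNA, are outside this count. Of 15 genes on the snRNA list the annotation named only Rnu3a, while the peak in Rnu7 was named for Grcc10, whose 5′ UTR it overlaps.

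The height of peaks was compared among bound genes only, and as a fold over input it can still depend on input coverage. In 9 lists with at least 5 bound members, 2 differed from other bound genes. Ribosomal protein genes had lower highest peaks, with a mean of 3.95 ± 0.55 (SD, 11 genes) against 5.35 ± 0.95 in 448 others (difference −1.40, permutation p = 1e-05, the smallest possible, adjusted p = 9e-05). snoRNA hosts were also lower, at 4.24 ± 0.73 in 13 genes against 5.35 ± 0.95 (difference −1.11, permutation adjusted p = 0.000315). Both lists share members and owe their peaks largely to snoRNAs. T cell identity genes stood at 5.94 ± 0.42 against 5.31 ± 0.97 (7 genes, difference 0.63, permutation adjusted p = 0.25) and hnRNP genes at 5.85 ± 0.77 (8 genes, difference 0.55, permutation adjusted p = 0.251), without passing the test. Differences in the cytokine receptor and JAK-STAT (−0.29), SR (−0.092), long noncoding RNA (0.54), translation factor (0.035) and chromatin regulator (0.21) lists did not pass it either, with permutation adjusted p values from 0.373 to 0.918. Without peaks in small RNA genes, the snoRNA host difference was −0.66 (permutation adjusted p = 0.368), and ribosomal protein genes, with 2 bound members left, could not be tested.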

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

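Added after the data were examined were the joined sites, the removal of short or small RNA peaks, RefSeq coordinates and all position settings. No paired analysis was possible because each peak has 1 value for both replicates; for the same reason nothing was run without replicate 1 or replicate 2. Base coverage, GC content, 5-mers and the RNA family comparison were not run either. Intron share, 59.1% as reported, was 51.2% when any 1-nt overlap counted and small RNA genes came first. It was 54.7% in the same order when at least as much of the peak had to lie inside a feature as outside. Under the 1-nt rule, 42 intronic peaks went to small RNAs and 29 to noncoding exons. The other rule moved 42 to small RNAs and 24 to noncoding exons, and brought 26 other peaks into introns. The count of 42 was thus the same under either overlap rule, while the gap between 51.2% and 54.7% came from that rule. Noncoding exon share (12.3%) was 7.90% at the stricter log2 fold, 9.31% in joined sites and 7.79% without peaks under 30 nt. Small RNA share (8.89%) was 5.27% at the stricter fold and 6.78% with RefSeq coordinates. The share within 1 kb of a 5′ end (53.3%) was 68.7% from the nearest transcript start. Lists above background numbered 14, and 12 to 14 in the alternatives. Lists differing in peak height fell from 2 to 0 without small RNA peaks, where ribosomal proteins had too few members to be tested. Results that changed sign had not passed their test: splice-site-near introns without small RNA peaks (0.038), 3′ UTRs with every peak counted once (0.12) and in joined sites (0.16), ribosome biogenesis at the stricter fold and without small RNA peaks (odds ratio 0 in both), histones with length matching (5.41), and, with the mean of a gene's peaks, SR factors (0.0063), long noncoding RNAs (−0.010), translation factors (−0.15, and −0.10 without small RNA peaks) and chromatin regulators (−0.043). Among single classes and lists, 119 further values kept their direction and their side of the threshold, 7 lost a call and 1 gained one. The cause was not tested. Absent read counts limit all statements to peaks the authors kept.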

Other observations

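All tests in this part were chosen after the values were seen. The Ski relative Skil had 1 peak near a splice site at a log2 enrichment of 4.87 (chromosome 3, 31095238 to 31095353) and the inhibitory gene Smad7 had 1 coding exon peak at 5.62 (chromosome 18, 75369072 to 75369126). Both genes act in TGF-β signalling, were picked by eye and belong to no tested list. The 1 peak on chromosome Y, at 991710 to 991741 with a log2 enrichment of 5.13, lay in n-R5s1, 1 of 17 rRNA gene copies with a peak, although the mice were female. Cells of female mice carry no chromosome Y, so these reads must stem from another place. Other peaks in repeated RNA genes may be misplaced likewise, which was not tested.

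The crowding of peaks at 5′ ends has several candidate explanations. Without the 12 genes with the most peaks, 344 of 612 peaks (56.2%) still lay within 1 kb of the start, against 4.69% for uniform placement. These genes held too few of the 722 peaks for the share to fall to the uniform level, so this outcome was fixed in advance. The crowding was not confined to the 12 genes, but the step is no test of its source. A smooth fall of precursor RNA along long genes would make intronic peaks about as dense in the first kb as in the next 4 kb. In genes over 50 kb, 90 had such a peak only in the first kb and 11 only in the next 4 kb (89.1%, 81.3 to 94.4, where even density gives 20%), which argues against it as the whole cause. A first version of this test, on peaks beyond 5 kb, gave 58.0% in the first 50% of the gene (49.8 to 65.8) against 47.2%, so a part played by such a fall stays open, as do GC-rich sequence and short promoter-proximal RNAs, which were not tested, and no biological explanation was tested.

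The most enriched intronic peaks may be of another kind than the rest. Of the 12 most enriched genes, the 9 with a site in a protein-coding intron outside snoRNA, scaRNA, snRNA and rRNA genes (so without Gm26636 and 9330185C12Rik) had a median span of 29 nt against 83 nt in 241 other genes (difference −54), and a −log10 p of 13.5 to 400 against a list median of 12.3. The short span drew attention to them, so it does not decide whether they are of the same kind. Unannotated small RNA copies (the Peak1 site overlaps Gm24270, an annotated one) could lie away from gene starts, and 33.3% of the 9 lay within 1 kb against 57.7% (Fisher's exact p = 0.18), too few sites to decide. An earlier choice, sites of up to 60 nt with a −log10 p of at least 20 in single-site genes against longer sites with no such limit, gave a difference in median position of 0.18 (17 and 116 sites, permutation p = 0.00157), but its limits were set on seen values, so it is not relied on, and no biological explanation was tested.

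The peaks of Gm26917 and Gm42418 beside Rn18s-rs5 (chromosome 17, 39846354 to 39848202) may come from reads of ribosomal RNA placed at this locus. Deep coverage in IP and input alike would give ceiling p values at low enrichment, and 100% of the 37 peaks stood at the ceiling against 4.06% of 863 others, with a median log2 enrichment of 3.55 against 5.35. The 37 peaks are pieces of 11 sites at 1 locus and these values prompted the idea, so they are no test of it. An abundant RNA of the locus itself would look alike, and the source stays open. No biological explanation was tested.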
